A study of Mus musculus with 6 samples.

How the data were processed

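RNA was measured in alveolar epithelial type II (AT2) cells, the surfactant-making cells of the lung alveolus, from C57BL/6 mice. Per the labels' protocols, lungs were digested with dispase and CD45-negative, EPCAM-positive cells were taken by magnetic sorting. All mice carried a tamoxifen-inducible Cre recombinase at the surfactant protein C gene and floxed alleles of Grp78, the chaperone encoded by Hspa5. By their genotype labels, the 3 control libraries came from mice not given tamoxifen and the 3 libraries labelled knockout from mice given it, in which case tamoxifen and the knockout cannot be separated. The day label of all 6 samples, controls included, counts 10 days from a tamoxifen injection, which conflicts with the genotype label of the controls, so whether the controls received tamoxifen is in doubt. Nothing in the labels says that the replicates were separate animals, so p-values measure the spread between these samples, which may be technical.

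The authors deposited one table of raw gene counts with gene symbols, made from paired reads of a NEBNext Ultra RNA library. Per the submitters' processing notes, the genome build was mm10 and edgeR 3.7 was used; the aligner, the counting program and the annotation are not given in the sources used here. The deposited counts held 52550 genes, of which 48018 matched a symbol in GENCODE M21, the annotation from which coordinates on the same build were taken. A count of 2 was 1.63 to 1.76 times as common as a count of 1 in every library, as when each mate of a read pair is counted separately. Counting errors are therefore larger than the counts alone imply. The labelled kit does not state strand, so overlapping and antisense genes cannot be told apart.

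Library totals ranged from 110770711 to 149520306 counts. Differential expression was computed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, robust dispersion estimates and the quasi-likelihood F test, with group as the only term. Adjusted p-values are Benjamini-Hochberg values from this test over the 18849 genes tested, and a gene was called at an adjusted p under 0.05. Values per library are CPM scaled by TMM. Log2 folds are the libraries labelled knockout over controls, and the standard error (SE) is the log2 fold divided by the square root of F. The common biological coefficient of variation was 22.3%.

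The design, the alternatives, 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took Hspa5; the 8 largest rises and 8 largest falls among called genes with separate groups and at least median expression; the 4 members of each list with the lowest adjusted p; and 13 genes set in advance. The text names part of these, 6 called genes are not reported here, and members of lists named only because 5 or fewer of a list moved one way were chosen after their values were seen. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Each was adjusted over the lists. The estimated correlation rests on only 6 libraries, and with it camera uses far fewer degrees of freedom. A weaker result under that setting therefore need not come from correlation between genes. A list entry without a row in the table was not analysed here.

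Deviations from group means correlated across genes at 0.174, 0.147 and 0.281 between same-numbered libraries. All exceeded 0.1, but the labels do not say what the numbers mark, and the main fit kept group as its only term. Libraries numbered 1 and 2 also correlated across groups at 0.0897 and 0.116, while libraries numbered 3 correlated with the others at -0.227 to -0.181. The values show the libraries numbered 3 standing apart and do not settle whether the other numbers mark pairs. No 2 libraries agreed within sampling noise: chi-square per gene was 8.29 to 178 on halved counts. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, the replicate number as a block, and leaving out each library. Alternatives for normalized values did not apply to a count table.

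The scripts were tested on simulated counts of 18849 genes with known changes in 225, under 3 dispersion models. With the dispersion fitted to each gene, edgeR called 137 genes, of which 14.6% were false, and recovered 22.4%, 55.2% and 74.2% of changes of 1.5, 2 and 4-fold. With a trended dispersion and chi-square spread between genes it called 67, of which 8.96% were false, and recovered 2.99%, 26.9% and 50% of them. Both missed bounds guessed beforehand, which asked for over 80% recovery of 4-fold changes (lowered to 70% after the first run) and under 10% false calls. The third model, trended dispersion alone, was added after those failures: 6.02% of 133 calls were false and 32.8%, 49.3% and 83.3% of changes were recovered. With edgeR the false share exceeded the 0.05 threshold in all 3 models, and with DESeq2 it was 21.0% to 48.2%. Every true call had the right direction, and median estimated folds lay close to those simulated. None of 30 unchanged lists was called, but their genes were simulated as independent, which real lists are not. A list of independent genes raised 2-fold was called by camera with an estimated correlation in all 3 models (camera adjusted p = 0.00434, 0.0122 and 0.00646). Far fewer genes were changed in the simulations than were called in the real comparison, whose false share they do not give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.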

Results

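Gene expression was measured by RNA sequencing in mouse AT2 cells, with 3 control libraries and 3 libraries labelled Grp78 knockout. The series asks how AT2 cells that lack Grp78, the main chaperone of the endoplasmic reticulum (ER), differ from AT2 cells that keep it. Controls 1, 2 and 3 held 131235053, 149520306 and 134215811 counts. Libraries 1, 2 and 3 labelled knockout held 128129307, 110770711 and 123195011 counts. The 10 most abundant genes took 21.3% ± 0.845 (SD, n = 3) of the counts in controls and 13.9% ± 0.291 (SD, n = 3) in the libraries labelled knockout.

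Hspa5, which encodes Grp78 (chromosome 2, 34771970 to 34777547, plus strand, mm10), was 6.24-fold higher in the libraries labelled knockout, although the label names a loss of this gene. Its normalised CPM was 1355, 1289 and 925 in controls 1, 2 and 3. In libraries 1, 2 and 3 labelled knockout it was 9262, 9180 and 3809. The log2 fold was 2.64 (SE 0.361, edgeR adjusted p = 0.00208). Gene-level counts do not separate the floxed exons from the rest of the gene, so they cannot check whether the allele was recombined. The rise therefore neither bears out nor contradicts the label. Every direction given here is one between libraries as they are labelled.

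Of 18849 genes tested, 6938 (36.8%) were called by edgeR, 3391 higher and 3547 lower in the libraries labelled knockout. Of the called genes, 1551 were higher and 846 lower by 2-fold or more. The groups did not overlap for 9726 tested genes (51.6%), against 10% by chance for 3 libraries against 3. Leaving out control 2, library 1 labelled knockout or library 2 labelled knockout lowered the count to 3706, 3981 and 3779. Leaving out both libraries numbered 3, an alternative chosen after seeing the data, raised it to 10581. With scaling by library size alone, 82.2% of calls were higher against 48.9% with TMM, and the median gene moved by 0.26 on the log2 scale; with upper-quartile factors 59.2% were higher.

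Genes of ER protein folding and of the integrated stress response rose together. Of 26 ER chaperone and folding genes, 19 were higher and 1, Cnpy2, lower, with a median log2 fold of 0.99. Hsp90b1, the ER member of the HSP90 family, rose from 909 ± 31.9 to 5178 ± 1717 CPM (SD, n = 3 per group; log2 fold 2.51, SE 0.266, edgeR adjusted p = 0.000893). Creld2 rose by a log2 fold of 3.55, Sdf2l1 by 3.26 and the disulfide isomerase Pdia4 by 3.10. Of 35 targets of ATF4 and the integrated stress response, 26 were higher and 1, Vldlr, lower, with a median of 1.51. The cationic amino acid transporter gene Slc7a3 rose by a log2 fold of 6.64, the mitochondrial folate enzyme gene Aldh1l2 by 4.48, Trib3 by 3.87 and Gdf15 by 3.80. Of 27 genes of ER-associated degradation and translocation, 12 were higher and 1 lower (median 0.43). Derl3 rose 59.6-fold (log2 fold 5.90, SE 0.398, edgeR adjusted p = 0.000397), and Sel1l, Syvn1 and Edem1 rose by log2 folds of 1.91, 1.74 and 1.56.

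Among 13 sensors and transcription factors of the unfolded protein response, 4 were higher and 4 lower. Ddit3, which encodes CHOP, rose 24.6-fold from 9.73 ± 2.61 to 239 ± 116 CPM (SD, n = 3). Atf4 (log2 fold 1.57), Atf6 (0.86) and Eif2s1 (0.57) were also higher, and Creb3l1 (-0.67), Ern1 (-0.37), Atf6b (-0.36) and Mbtps1 (-0.35) were lower. Xbp1 had a log2 fold of -0.07 (SE 0.228, edgeR adjusted p = 0.815), with the groups overlapping. The list's median was -0.07 and its mean 0.42, of opposite sign, and it was not called by camera (adjusted p = 0.931). Camera called the chaperone, ATF4 and degradation lists at adjusted p = 5.28e-06, 1.63e-09 and 0.000963, but with an estimated correlation the adjusted p was 0.50, 0.451 and 0.737; fry did not call the degradation list (adjusted p = 0.067). Counted over the list alone, 19, 29 and 12 members of these lists were higher. In library 3 labelled knockout the rise was smaller, with a median chaperone gene 0.45 above the control mean on the log2 scale against 1.20 and 1.21 in libraries 1 and 2. With 1 library left out, 12 to 20 chaperone and 6 to 18 degradation genes were higher, and 2 to 6 of the sensors and transcription factors lower. The calls of Cnpy2, Vldlr, Eif2s1, Ern1 and Mbtps1 ended when 1 library was left out. Those of Cnpy2, Vldlr, Ern1, Mbtps1, Creb3l1 and Atf6b ended with library-size scaling.

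**Figure D1:**
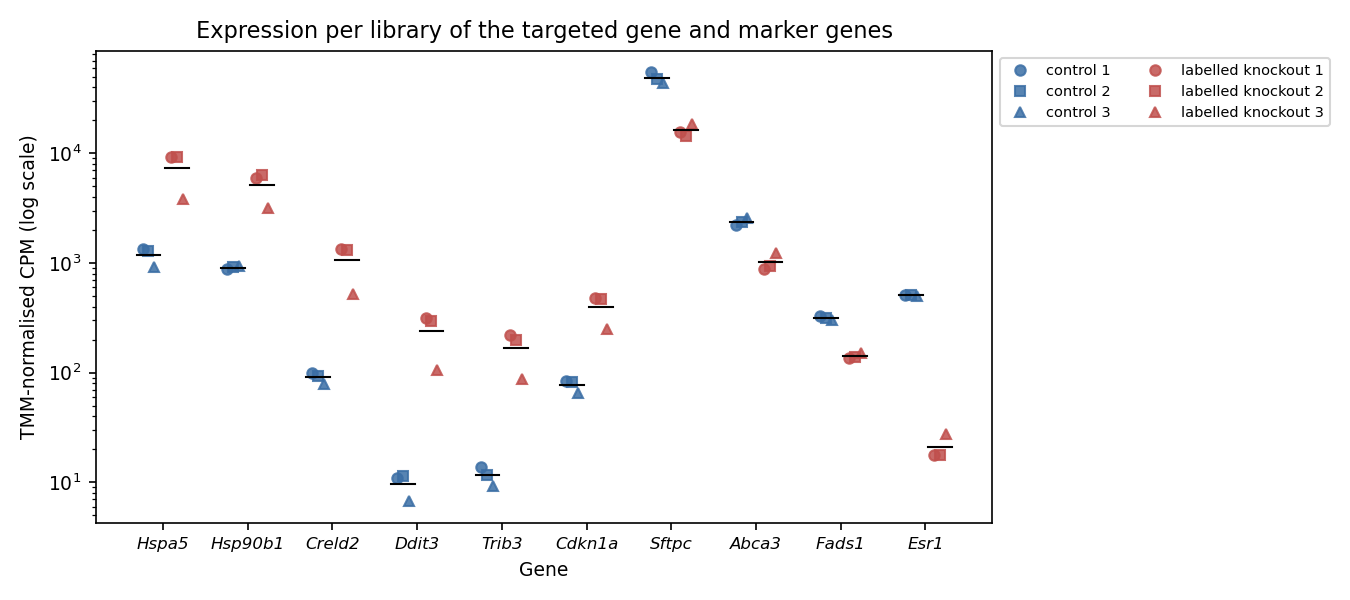
TMM-normalised CPM on a log axis for 10 genes in each of the 6 libraries, blue for controls and red for libraries labelled knockout, with the marker shape giving the replicate number and a black bar the group mean. Hspa5 lies between 925 and 1355 in controls and between 3809 and 9262 in the libraries labelled knockout, and Esr1 falls from 509 to 21.2.

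Markers of AT2 identity and genes of lipid synthesis fell. Of 28 AT2 markers, 27 were lower, the exception being Ctsh (log2 fold -0.36, edgeR adjusted p = 0.0643, or 0.0215 with the replicate block), and the median log2 fold was -1.26. Sftpc, the surfactant protein C gene and the locus of the Cre transgene, fell 3.01-fold (log2 fold -1.59, SE 0.194, edgeR adjusted p = 0.00137). Abca3, the lamellar body lipid transporter gene, fell by 1.23 on the log2 scale, the transcription factor gene Cebpa by 1.20 and Lgi3 by 1.83. Of 37 genes of surfactant lipid and sterol synthesis, 25 were lower and 1, Elovl6, higher, with a median of -0.69. Idi1 fell by 1.19 and Fads1 by 1.14 on the log2 scale. Camera called both lists lower (adjusted p = 7.60e-13 and 6.82e-10). With an estimated correlation the lipid list held (camera adjusted p = 0.0477) and the AT2 list did not (camera adjusted p = 0.377). The estimate for the lipid list was -0.0022, below the preset 0.01, so correlation did not cause its weaker adjusted p. For the AT2 list the estimate was 0.552. Over all lists that lost their camera call under this setting, estimates ran from 0.0288 (senescence) to 0.962 (ribosomal), above the preset. For those lists, correlation between genes as a cause is not excluded. Over the list alone 28 AT2 markers and 26 lipid genes were lower. The Elovl6 call ended when 1 library was left out.

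Most targets of p53 and secretory senescence genes were higher, and cytokine and interferon response genes were more often called higher than lower. Of 26 p53 targets, 17 were higher and 4 lower (Sesn1, Btg2, Rrm2b and Dcxr), with a median of 0.83. The cyclin-dependent kinase inhibitor gene Cdkn1a rose from 77.5 ± 10.1 to 401 ± 129 CPM (SD, n = 3), and Phlda3 and Eda2r rose by log2 folds of 2.67 and 2.72. Of 31 senescence and secretory genes, 19 were higher and 1, Igfbp7, lower (median 0.81); Plaur rose by 2.83. Of 32 cytokine and chemokine genes, 13 were higher and 4 lower (Csf2, Il33, Nfkb1 and Cxcl15), with a median of 0.94. Lcn2 rose by a log2 fold of 1.54, and Csf2 fell by 1.52. Of 28 interferon response genes, 13 were higher and 2, Irf1 and Ifih1, lower (median 0.76), with Isg15 at 1.71 and Tap1 at 0.97. Leukocyte marker genes summed to 375 CPM in library 3 labelled knockout and to 49.3 to 72.9 CPM in the other 5. Of 24 apoptosis genes, 11 were higher, among them Bax (2.03) and Bak1 (0.73), and 5 lower (Bik, Dapk1, Bcl2l11, Mcl1 and Xiap).

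Camera called the p53, senescence, cytokine and interferon lists (adjusted p = 0.000116, 1.31e-06, 0.0042 and 0.000137). With an estimated correlation the adjusted p was 0.377, 0.199, 0.377 and 0.415. Camera did not call the apoptosis list (adjusted p = 0.156), while fry called it higher (adjusted p = 0.00591). Over the list alone, 17, 20, 13, 17 and 11 members of the p53, senescence, cytokine, interferon and apoptosis lists were higher, and 4, 1, 4, 2 and 7 lower. The senescence and cytokine lists share 6 genes and the p53 and apoptosis lists 5. The cytokine list was not called with library-size scaling (adjusted p = 0.0533) or the 5 CPM filter (adjusted p = 0.659). With 1 library left out, 7 to 13 apoptosis genes were higher. The calls of Mcl1, Dcxr, Il33, Ifih1 and Irf1 ended when 1 library was left out, that of Il33 also with the replicate block (edgeR adjusted p = 0.0512).

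Mesenchymal genes and genes of the transitional alveolar epithelial state were higher, while TGF-beta genes went both ways. Of 24 mesenchymal and epithelial-mesenchymal transition genes, 18 were higher and 2, Col4a1 and Col4a2, lower, with a median of 1.72. Tnc, an extracellular matrix gene, rose 33.3-fold (log2 fold 5.06, SE 0.158, edgeR adjusted p = 1.86e-05), Fn1 by a log2 fold of 2.51 and Vim by 1.57. Of 28 transitional genes, 20 were higher and 1, Sox4, lower (median 0.97), with Ndrg1 at 3.40 and Tubb6 at 2.32. Krt8, a keratin gene of that state, rose by only 0.48 (edgeR adjusted p = 0.0317). Of 31 TGF-beta genes, 8 were higher and 7 lower; Ltbp2 rose by 1.55 and Bambi, a pseudoreceptor gene, fell by 1.62. Tgfb1 had a log2 fold of -0.09 (edgeR adjusted p = 0.546), and 0.17 with library-size scaling. Of 24 AT1 markers, 8 were lower and 2, Pdpn (1.06) and Spock2 (0.53), higher, with 5 higher under the replicate block. Ager fell by 1.31, and Hopx had a log2 fold of 0.41 (edgeR adjusted p = 0.0567, or 0.00466 with the block).

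Camera called the mesenchymal and transitional lists (adjusted p = 1.34e-06 and 4.67e-07), at adjusted p = 0.377 for both with an estimated correlation. It did not call the TGF-beta list (adjusted p = 0.886) or the AT1 list (adjusted p = 0.221), which fry called lower (adjusted p = 0.0175). Over the list alone, 19 mesenchymal, 21 transitional and 10 TGF-beta genes and 5 AT1 markers were higher, and 2 mesenchymal, 2 transitional and 9 TGF-beta genes and 10 AT1 markers lower. The mesenchymal list shares 5 genes with the fibroblast list. With 1 library left out, 4 to 10 TGF-beta genes and 5 to 10 AT1 markers were lower, and 1 to 6 AT1 markers higher. The calls of Krt8, Col4a1, Col4a2 and Spock2 ended when 1 library was left out.

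Markers of fibroblasts, smooth muscle and mesothelium were higher, and those of airway, endothelial and red cells were mostly not called. Of 26 fibroblast and smooth muscle markers, 22 were higher and none lower (median 1.47; limma-voom and DESeq2 called none lower either, and 0 were lower at an unadjusted p under 0.05); Col6a3 rose by 2.72, Des by 2.52, Acta2 by 2.14 and Mfap4 by 1.49. In control 3 the median marker lay 0.45 above the control mean. Of 8 mesothelial markers, 7 were higher, the exception being Muc16 (log2 fold 0.51, edgeR adjusted p = 0.0893, or 0.0102 with the replicate block). Of 25 airway markers, 3 were higher (Tmem212, Cdhr3 and Calca) and 1, Cbr2, lower; without control 3, 2 were higher and 8 lower. Of 22 endothelial markers, 1 was higher (Vwf) and 1 lower (Aplnr), with 2 each way under the block; without library 3 labelled knockout, 10 were higher and 2 lower. Of 27 leukocyte markers, 2 were higher, Mrc1 (2.56) and C1qc (5.55), although the sort was for CD45-negative cells. Without library 3 labelled knockout both calls held with smaller folds (1.16 and 1.56) and 2 markers were lower; without any 1 of the controls both calls ended, and limma-voom called 0 leukocyte markers (1 higher and 1 lower at an unadjusted p under 0.05). Ptprc, which encodes CD45, was at 10.99 CPM in library 3 labelled knockout and 0.963 to 2.07 elsewhere (log2 fold 1.56, edgeR adjusted p = 0.216). Epcam fell by 0.33 (edgeR adjusted p = 0.025). Of 9 erythroid markers, 1 was lower, with 4 higher as well without library 3 labelled knockout, and the list's median (0.59) and mean (-0.09) differ in sign.

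Camera called the fibroblast and mesothelial lists (adjusted p = 2.94e-08 and 0.000445), at 0.415 and 0.377 with an estimated correlation. Neither camera nor fry called the airway, endothelial, leukocyte and erythroid lists (camera adjusted p = 0.895, 0.369, 0.118 and 0.911). With the replicate block the leukocyte list was called (adjusted p = 0.0108, 8 members higher and 1 lower), and C1qc was not (edgeR adjusted p = 0.0533). Without library 3 labelled knockout the leukocyte list's direction was reversed (adjusted p = 0.955) and the endothelial list was called (adjusted p = 0.00314). Over the list alone, 22 fibroblast, 8 mesothelial and 3 airway markers were higher, and no leukocyte or endothelial marker passed, although 9 leukocyte markers were higher and 1 lower, and 4 endothelial markers higher and 2 lower, at an unadjusted p under 0.05. The calls of Epcam, Mrc1, Vwf, Cbr2, Calca, Cdhr3, Aplnr and C1qc ended when 1 library was left out.

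Cell cycle genes were higher and mitochondrially encoded genes lower. Of 32 cell cycle genes, 21 were higher and none lower (limma-voom and DESeq2 called none lower either, and 0 were lower at an unadjusted p under 0.05), with a median of 1.29; Aurka rose by 1.82 and Mcm7 by 0.79. Control 3 lay 0.67 above the control mean for the median gene of this list. Of 13 mitochondrially encoded genes, 10 were lower (median -0.71), with mt-Nd2 down by 0.87 and mt-Nd5 by 0.76; mitochondrial genes took 5.15% ± 0.53 of counts in controls and 3.90% ± 0.343 in the libraries labelled knockout (SD, n = 3). Of 27 proteasome genes, 5 were higher (Psmc2, Psmd14, Psma5, Psmb6 and Psmc1), and of 30 ribosomal protein genes 8, among them Rplp0 (1.01). With the replicate block 22 proteasome genes and 22 ribosomal genes were higher. Of 27 nuclear-encoded oxidative phosphorylation genes, 3 were lower, among them Sdha and Ndufb3, and 1, Cox5a, higher, with 10 higher under the block. Of 24 immediate early genes, 11 were lower, with Jun down by 0.90 and Fosb by 0.98, and 4 higher (Myc, Nr4a2, Ier5 and Fosl2). Myc rose by a log2 fold of 3.21.

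Of 20 cytosolic heat shock genes, 3 were lower, Hsph1, Dnaja1 and Dnajb4, with 2 higher and 4 lower under the block, which ended the calls of Dnaja1 and Dnajb4 (edgeR adjusted p = 0.0736 and 0.063). The list summed to 12575 and 12917 CPM in controls 1 and 2 and to 4883 CPM in control 3. Without control 3, 14 of these genes were lower and camera called the list (adjusted p = 2.48e-07). Of 26 genes of oxidative stress and NRF2, 7 were higher, with Mt2 at 2.17, and 3 lower (Cat, Tkt and G6pdx), with 5 lower under the block. Of 26 autophagy and lysosome genes, 7 were lower and 5 higher, among them Sqstm1, Ctsd, Ctsl and Wipi1. Of 24 Wnt, Notch and Hippo targets, 10 were lower, with Notum down by 2.89, Nkd1 by 1.12 and Notch2 by 1.02, and 6 higher, among them Ctgf (0.97).

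Camera called the cell cycle, mitochondrial, proteasome and ribosomal lists (adjusted p = 3.28e-08, 2.23e-05, 0.000859 and 0.00179). With an estimated correlation the adjusted p was 0.451, 0.473, 0.771 and 0.771. Without control 3 the ribosomal list was not called (adjusted p = 0.0671). No proteasome or ribosomal gene passed in edgeR without control 2, control 3, or library 1 or 2 labelled knockout, although 2 to 6 proteasome and 7 or 8 ribosomal genes were higher at an unadjusted p under 0.05; without library 3 labelled knockout, 20 of each were higher. Fry did not call the proteasome and ribosomal lists (adjusted p = 0.177 and 0.257). Camera did not call the lists of oxidative phosphorylation, immediate early, heat shock, NRF2, autophagy and Wnt genes (adjusted p = 0.422, 0.14, 0.117, 0.339, 0.229 and 0.257); fry called the Wnt list lower (adjusted p = 0.00165) and none of the other 5. Over the list alone, 25 cell cycle genes were higher, 12 mitochondrial genes lower and 4 ribosomal genes higher, and no proteasome or heat shock gene passed, although 15 proteasome genes were higher, and 8 heat shock genes lower and 1 higher, at an unadjusted p under 0.05. With 1 library left out, 4 to 13 mitochondrial genes, 0 to 4 oxidative phosphorylation genes, 2 to 7 NRF2 genes (7 without control 3) and 6 to 11 Wnt, Notch and Hippo targets were lower, and 3 to 6 of those targets, 2 to 5 immediate early genes and 0 to 7 of the oxidative phosphorylation genes higher. Autophagy genes ranged from 0 to 11 lower and 2 to 6 higher, with 0 lower without library 1 or 2 labelled knockout (7 and 8 at an unadjusted p under 0.05) and 11 without library 3. The calls of the named proteasome, ribosomal and oxidative phosphorylation genes, and of Hsph1, Dnaja1, Dnajb4, Ier5, Fosl2, G6pdx, Ctsl and Wipi1, ended when 1 library was left out.

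**Figure D2:**
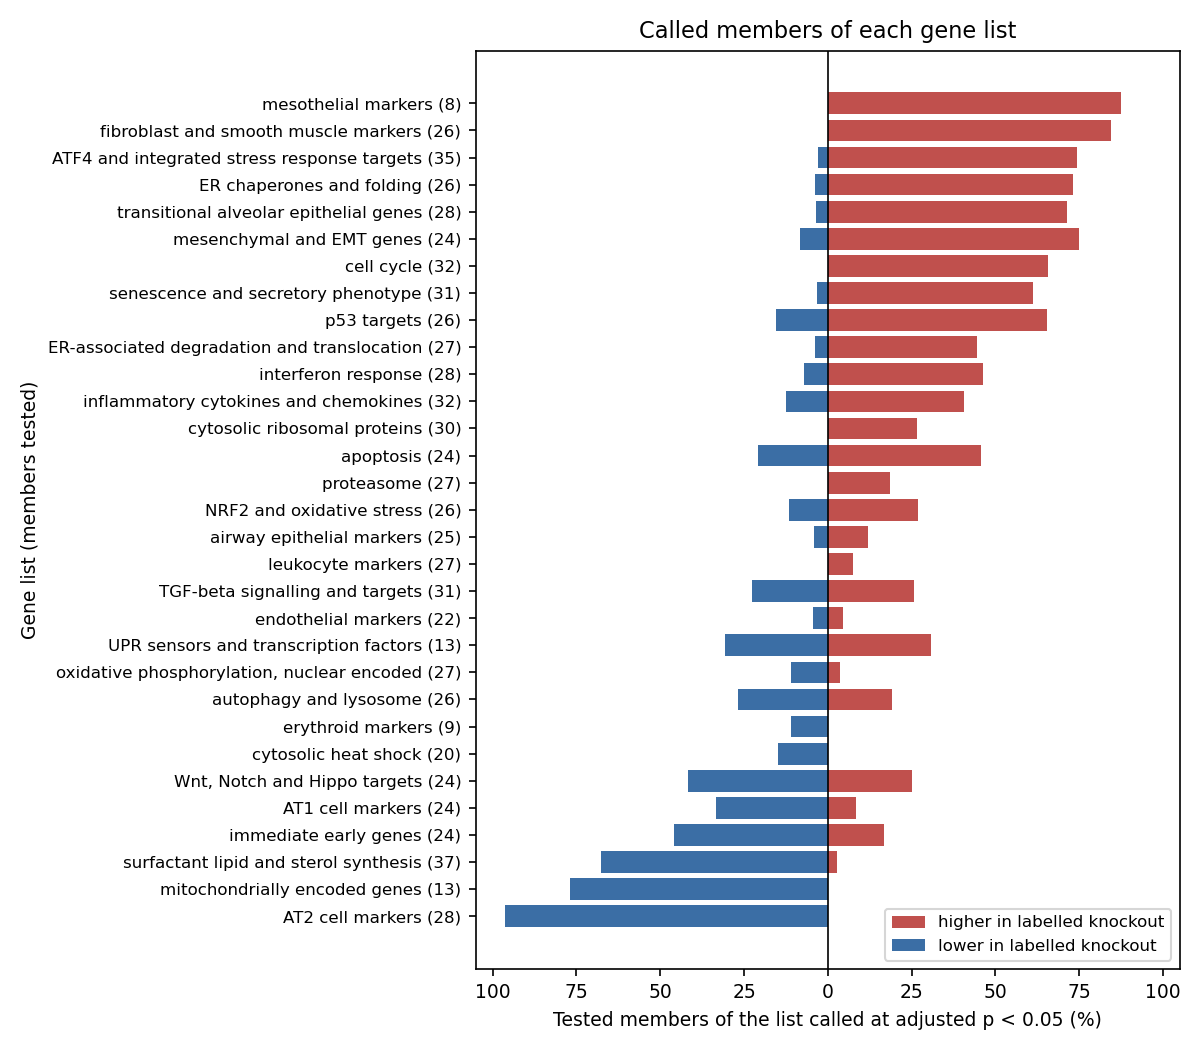
Share of the tested members of each of the 31 gene lists called higher (red, right) or lower (blue, left) in the libraries labelled knockout, in percent of members tested, with the number tested in brackets. AT2 markers show 27 of 28 members lower, and fibroblast and smooth muscle markers 22 of 26 higher.

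Among called genes with separate groups and at least median expression averaged over all libraries, the largest rises after Slc7a3 included Spp1 and Avil. Spp1, which encodes osteopontin, rose 64.1-fold (1.37 ± 0.331 to 87.6 ± 10.2 CPM, SD, n = 3), and Avil rose 60.5-fold. Levels in controls were low, with means of 0.216 CPM for Slc7a3 and 0.803 CPM for Avil, so these folds rest on small denominators. Slc7a11, the cystine transporter gene, rose 23.8-fold. A row with the symbol Dlg2_2 rose 62.6-fold, but the symbol matched no annotated gene and its identity is uncertain. The largest fall was of the oestrogen receptor gene Esr1 (chromosome 10, 4611593 to 5005614, plus strand, mm10), 24.0-fold lower. Its CPM was 515, 511 and 501 in controls 1, 2 and 3 and 17.9, 17.8 and 27.9 in libraries 1, 2 and 3 labelled knockout (log2 fold -4.58, SE 0.211, edgeR adjusted p = 9.87e-05). The inducible Cre recombinase is fused to a part of the oestrogen receptor, and gene-level counts cannot separate transgene reads from those of Esr1. The next largest falls were of Hes2 (-2.91), Notum (-2.89), Vsig2 (-2.70), Tmod1 (-2.68), Snx22 (-2.49), Dgkg (-2.38) and Tinag (-2.35).

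**Figure D3:**
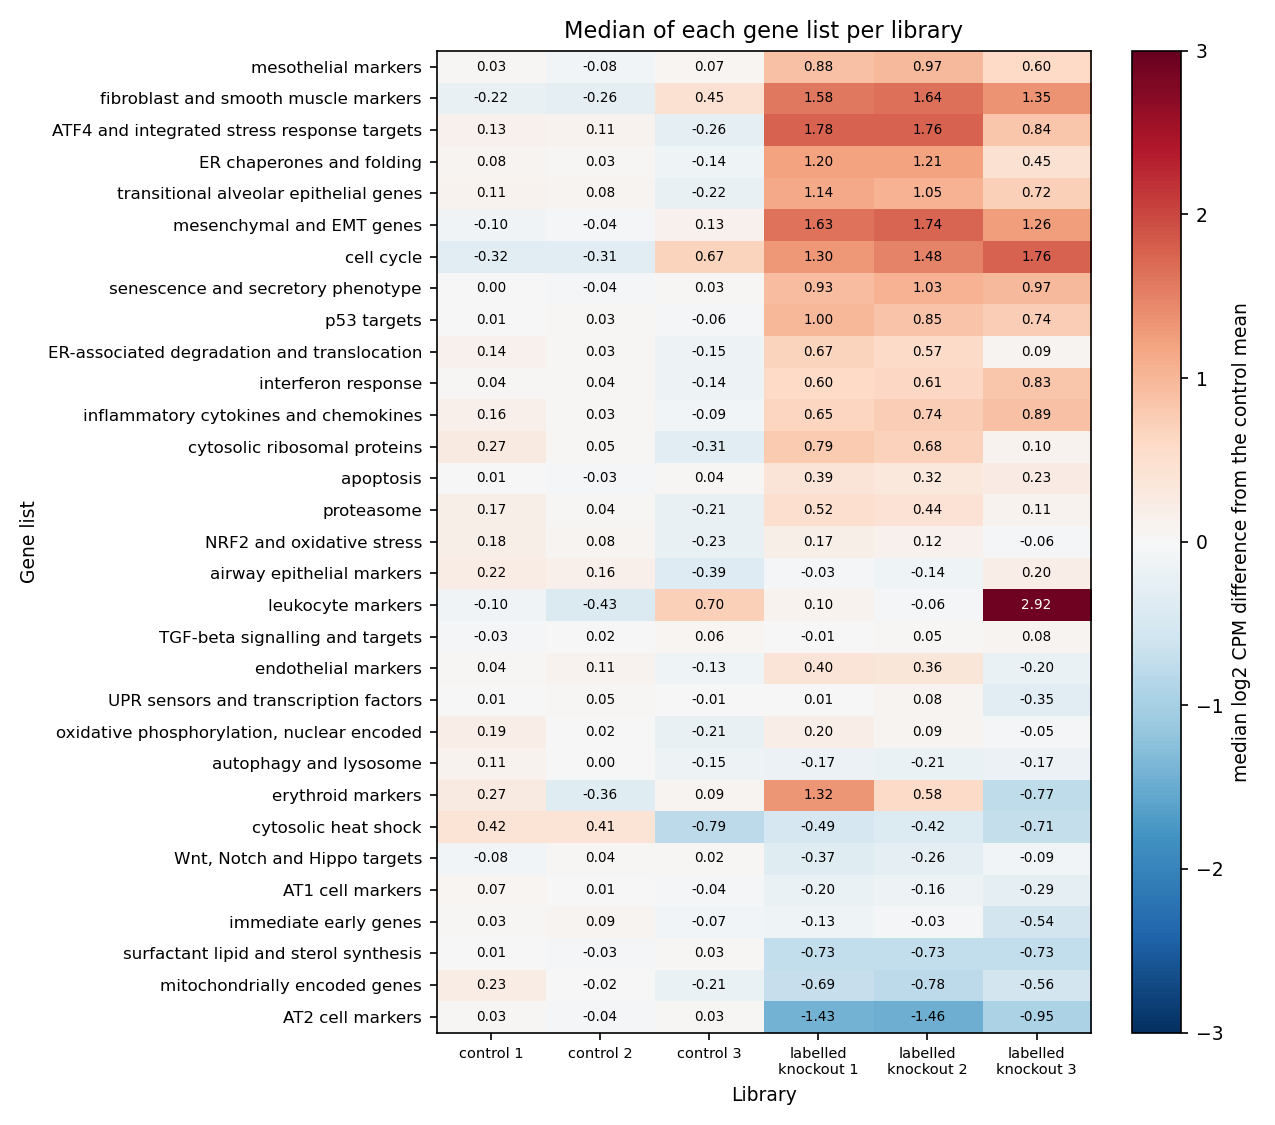
Median log2 CPM difference from the control mean over the members of each gene list (rows) in each library (columns), with red for higher and blue for lower. Leukocyte markers stand at 2.92 in library 3 labelled knockout, and AT2 markers between -1.46 and -0.95 in the libraries labelled knockout.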

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

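The alternatives without both libraries numbered 3 and with these 2 as a block were chosen after seeing the data. No gene called in both the main analysis and an alternative changed direction, and Hspa5 stayed higher and past the threshold in all 16 alternatives. Of 146 called genes followed through the alternatives, 93 passed in every alternative that tested them. Calls numbered 7878 with DESeq2, 6808 with limma-voom, 6232 with no filter, 8415 (4125 higher, 4290 lower) with the replicate block and 9393 with the libraries numbered 3 as a block. Among the genes followed, 26 lost their call with library-size scaling, 12 with upper-quartile factors and 15 with no filter. Several of these are given in the results only as lost with 1 library left out. The calls of Epcam, Mcl1 and G6pdx, for example, were also lost with both of these scalings. Beyond the genes with lost calls given in the results, Col1a1 lost its call with no filter or with 1 library left out. Bcl2l11, Sesn1, Nfkb1 and Sox4 lost theirs with library-size scaling. DESeq2 gave no adjusted p for Ptprc and C1qc. The block changed no call of a named gene or list beyond those given in the results. With library-size scaling 6218 genes were higher and 1343 lower. With 1 library left out the count ranged from 3706 to 8548, with 1684 to 4242 higher and 1881 to 4306 lower; smaller groups give less power, and the cause was not tested further. Without both libraries numbered 3 it was 10581, with 5355 higher. A threshold of adjusted p under 0.01 gave 3099 genes, and a log2 fold of at least 1 as well gave 2397. With an estimated correlation 1 list was called against 17; fry called 17, with 3 lists lost and 3 gained.

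Reversals concerned uncalled results, and their cause was not tested. The log2 fold of Xbp1 was 0.0029 with upper-quartile factors, 0.19 with library-size scaling and -0.29 to 0.078 with 1 library left out, above 0 without control 1 or library 3 labelled knockout (0.063). That of Tgfb1 was 0.17 with library-size scaling. That of Ptprc was -0.42 to 2.03 with 1 library left out, negative only without library 3 labelled knockout, and -0.10 without both libraries numbered 3. The following are adjusted p-values of lists. With library-size scaling the reversed unfolded protein response and airway lists stood at 0.886. With the 5 CPM filter the reversed response list was at 0.839 and the erythroid list at 0.505; with the replicate block both were at 0.964, and with the other block the response list was at 0.978. With 1 library left out the response list ranged from 0.67 to 0.971, reversed without control 2 (0.955) or library 3 labelled knockout (0.716). The airway list ranged from 0.153 to 0.955, reversed without control 3 or library 3 labelled knockout. The erythroid list (0.337 to 0.971) and leukocyte list (0.0174 to 0.955) reversed without library 3 labelled knockout. The NRF2 list (0.112 to 0.88) and oxidative phosphorylation list (0.0906 to 0.835) reversed without control 3 (0.88 and 0.758). Without both libraries numbered 3 the response, airway and erythroid lists reversed at 0.934, 0.13 and 0.58. With fry the erythroid list reversed at 0.995, and without genes in more than one list the TGF-beta list at 0.665. Alternatives for normalized values were not run because the table holds counts.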

Other observations

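The tests of fibroblast markers, of stress genes in library 3 and of Esr1 against Sftpc and AT2 markers were chosen after the results were seen; the counts over other splits of the libraries were planned.

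The following genes were picked after seeing the data, and their lists were not tested for enrichment. Of 9 MHC class II genes, 8 were lower, with a median log2 fold of -1.53; H2-Ab1 fell from 672 ± 38.1 to 172 ± 58.2 CPM (SD, n = 3) and H2-Aa by 1.82 on the log2 scale. Cd74, the invariant chain gene and one of the AT2 markers, fell by 1.55. Of 9 MHC class I genes, 2 were higher and 2 lower. Of 11 plasma cell genes, 6 were higher and 1 lower. The immunoglobulin gene Igha was at 5.48, 6.81 and 41.8 CPM in controls 1, 2 and 3 and at 148, 139 and 940 CPM in libraries 1, 2 and 3 labelled knockout (log2 fold 4.50, edgeR adjusted p = 0.0231). Jchain moved alike (4.50, edgeR adjusted p = 0.0169), and both calls ended without control 1 or control 2, or with no filter on low counts. Without library 3 labelled knockout the log2 folds of Igha and Jchain were 2.99 and 2.93, and without control 3 they were 6.04 and 5.62. The heat shock gene Hspa1b was at 858 and 847 CPM in controls 1 and 2, at 13.3 CPM in control 3 and at 62.6 to 74.1 CPM in the libraries labelled knockout.

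Fibroblast and smooth muscle markers were higher in the libraries labelled knockout. A lower share of AT2 cells, with the other cell types in fixed proportions, would raise markers of all of those alike. The fibroblast median exceeded the airway median by 1.47. The upper quartile of airway folds (0.45) lay below the lower quartile of fibroblast folds (1.03). Mesothelial, leukocyte, endothelial and erythroid medians were 0.76, 1.56, 0.21 and 0.59. These values argue against an equal rise, but not against a lower AT2 share in which the other cell types changed unequally. One carried-over stromal population would add all markers in one ratio. The interquartile range of log2 ratios of added amounts was 1.08 for library 3 against libraries 1 and 2, but 0.157 between libraries 2 and 1. Amounts added in library 3 ran from 0.036 (Tagln) to 1.62 (Cspg4) times those in libraries 1 and 2. The list pools fibroblast and smooth muscle markers, so stromal cell types that vary separately would also break one ratio. Only library 3 departed from one ratio. Carried-over stromal cells, which the EPCAM sort should remove, and expression of these genes in epithelial cells therefore cannot be told apart here. A change of the AT2 cells with the label remains open and was not tested separately from tamoxifen.

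Stress response genes rose less in library 3 labelled knockout. A larger share of cells without the change could give this, but it would shrink all changes alike, while library 3 kept a median share of 0.313 of the rise of stress genes and 0.82 of the fall of AT2 and lipid genes, a difference of 0.506. Dilution by leukocytes alone would lower AT2 markers, which were higher there by a median log2 of 0.46, in 25 of 28 above both other libraries. A weaker fall of the AT2 markers in that library would mask dilution, so dilution together with another cause is not excluded. An equal shift in both libraries numbered 3 is also against the values, since the drop was larger in library 3 labelled knockout than in control 3 by 0.672 on the log2 scale. The cause remains open.

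Esr1 counts fell 24.0-fold. Counts from the transgene at the Sftpc locus would follow Sftpc if its transcript moved with total Sftpc. Esr1 fell further by 2.99 on the log2 scale (SE 0.286). Sftpc was counted per gene, with its alleles pooled, so a separate loss of the transgene's transcript is not excluded. A lower share of AT2 cells, with expression per cell unchanged and markers confined to these cells, would lower Esr1 no further than AT2 markers. Esr1 fell further than Hc, the marker that fell most, by 2.60 (SE 0.401). That argues against such an equal loss. It does not exclude an unequal loss among AT2 cells, or markers also made by other cells. Tamoxifen, a ligand of the oestrogen receptor, may act on Esr1 itself. If, as their genotype labels say, 0 control libraries received it, its effect and that of the knockout cannot be told apart; the day labels of the controls, which count from an injection, put this in doubt.

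With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 6938 genes by edgeR and the highest of the other splits 0, although those had 46 to 1633 genes at an unadjusted p under 0.05. For gene lists, camera with its preset correlation called 17 in the real split and up to 19 in the others, and 6 of the 10 splits called at least 17. The number of lists called by camera therefore does not set the real grouping apart. Fry called 17 lists in the real split, 14 of them also called by camera, and 0 in each of the others. Every other split mixes libraries of both labels, so differences between the labels widen the spread within its groups. That works against calls by edgeR and fry, so their counts of 0 are no measure of false calls. A split cannot share 3 libraries of a label equally between its groups, so part of the label difference stays between them. The lists that camera called in the other splits are therefore no measure of false calls either. Of the 4 splits that part all 3 replicate numbers, the other 3 called 0 genes and 13 to 19 lists.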
